A study of Mus musculus with 2 samples.

How the data were processed

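Droplet-based single-cell RNA sequencing measured the polyadenylated RNA of CD45-positive cells, the surface mark of leukocytes, sorted by flow cytometry from tumors of mice bearing B16-F10, a mouse melanoma line. Mice received vehicle (Control) or DOPAC, 3,4-dihydroxyphenylacetic acid, a breakdown product of dopamine. The series' design gives 4 mice per group, but each group was deposited as 1 library without a tag that assigns cells to mice. A library was therefore treated as 1 sample, and its cells were not treated as replicates. The labels' protocol text speaks of colon tissue and captured beads, whereas the tissue label and the design text name tumors and the 10x Chromium instrument; the latter were followed.

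The deposited values are raw UMI counts per gene and cell barcode, as whole numbers without normalization, made with Cell Ranger 7.0.1 per the file headers and on the GRCm38 genome per the submitters' processing notes. Each library lists the same 32285 genes. The Control library held 9629 barcodes with 100938364 UMIs in total, and the DOPAC library held 10777 barcodes with 47769958 UMIs. The lowest barcode totals were 501 and 500 UMIs, so that the minimum of 500 UMIs used here removed no barcode.

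Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. The mitochondrial limit was exceeded by 1171 Control barcodes (12.2%) and 680 DOPAC barcodes (6.31%). Doublets were scored per library with Scrublet (in scanpy 1.11.5) at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 365 of 8444 Control cells (4.32%), which were removed. In the DOPAC library it marked 0.0% of 10095 cells, below the lowest accepted share of 0.5%, so the 815 cells with the highest scores (8.07%) were removed under the rule set for that case. Kept were 8079 Control and 9280 DOPAC cells.

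Both libraries were clustered together without integration. Each cell was scaled to 10000 UMIs and log-transformed, 2000 variable genes were chosen within the libraries, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0 were used (leidenalg 0.10.2, anndata 0.12.19, scikit-learn 1.9.0). Mitochondrial, ribosomal, T-cell receptor and immunoglobulin segment genes were left out of the variable genes. Clusters were named from fixed marker lists. A marker counted when its CPM (counts scaled to a common total) was at least 3 times that of the median cluster and it was found in at least 10% of the cluster's cells (25% for a marker of another lineage). A cluster took the name of its best list when at least 50% of that list and at least 3 markers counted. It was left unnamed when another lineage reached that share too or held more of the 10 leading genes, and was called shallow when its relative depth was below 1 in 3 of the library's median without a leading gene of its own lineage. T-cell clusters were clustered again and named from summed CPM: gamma delta genes of at least 500 CPM, Foxp3 of at least 50 CPM for regulatory T cells, and Cd8a plus Cd8b1 of at least 200 CPM and at least 10 times Cd4 plus Cd40lg for CD8 T cells. CD8 T subclusters with Mki67 plus Top2a of at least 500 CPM were kept apart as cycling, and a CD8 T subcluster with naive-cell genes of at least 500 CPM was called naive-like. These numerical naming thresholds were set after the data were seen, and a first version was revised because haemoglobin RNA had led to a macrophage cluster with C1q genes being called mixed. All class names below mean cells that resembled the class by these markers.

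Cell class shares were taken of all kept cells of a library with exact Clopper-Pearson 95% intervals, and differences in percentage points with Newcombe intervals. Expression was compared in each class with at least 100 kept cells in both libraries. UMIs were summed over the cells of a class per library and given as CPM of the summed UMIs with exact Poisson 95% intervals. The log2 ratio of DOPAC over Control was taken with 1 count added to each sum. A fold against 0 counts was taken against 3 counts over the class as a lower bound, and a share of 0 is given with the upper limit that 3 counts allow. All these intervals and limits cover counting error only. With 1 library per group no difference has a replicate check, and no test between treatments or p-value is given. Counts of genes at least 1.5-fold apart describe the 2 libraries and do not say how many genes the treatment changed.

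For 29 fixed gene lists, the median log2 ratio was taken over members with at least 20 UMIs in the 2 sums together, with the number of members at least 1.5-fold higher or lower. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes the 2 libraries and is not a test. The lists were NRF2 targets, NRF2 pathway, mitophagy, mitochondrially encoded genes, nuclear OXPHOS, glycolysis, hypoxia, cytotoxic effectors, T-cell exhaustion, T-cell naive and stem-like, T-cell activation, proliferation, interferon response, MHC class I, MHC class II, inflammatory myeloid, alternatively activated macrophage, chemokine receptors, heat shock and dissociation stress, apoptosis and p53, unfolded protein response, cholesterol and lipid, TGF-beta and residency, aryl hydrocarbon receptor, dopamine handling, small-subunit ribosomal proteins, melanoma cell RNA, erythrocyte RNA and nuclear-retained RNA. In 22 class and list pairs a measured member had 0 counts in 1 library. Setting such members at their 3-count bound left 11 of these medians as they were, and moved the largest, erythrocyte RNA in regulatory T cells, by 1.63.

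A gene could be named in a class when it had at least 50 UMIs in 1 library, at least 20 CPM and a UMI in at least 5% of cells in the higher library, and was not mitochondrial, ribosomal, a predicted gene, a receptor segment, haemoglobin, Xist or Y-linked. Genes at least 1.5-fold in 1 direction in every class where they were measured, in at least 3 classes, were called library-wide, and the 5 highest and 5 lowest of them were named. Of the rest, the 10 highest and 10 lowest were named in CD8 T cells and the 5 highest and 5 lowest in every other class. Up to 4 members of each list with the largest differences could be named too, and 12 genes of interest were always named in CD8 T cells: Pdcd1, Havcr2, Tox, Tcf7, Gzmb, Prf1, Ifng, Bnip3, Nfe2l2, Keap1, Hmox1 and Nqo1. For 15 fixed markers the share of CD8 T cells with a UMI was taken after each cell was thinned to 1000 UMIs, and shallower cells were left out; B cells served as background. Gene positions are GRCm38 coordinates from the GENCODE vM21 annotation, in which all 352 named gene identifiers were found.

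The filters, marker and gene lists, naming rule for genes, scalings and the alternatives called planned below were chosen before the data were examined. The alternatives covered the cell filter, doublet removal, clustering resolution and depth, a gate on Cd8 and Cd4 UMIs, scaling, thinning, the added count and the list minimum. The scaling alternatives moved the median log2 ratio of all genes by more than 0.1 in regulatory T cells (-0.24) and mature DCs (-0.11) with median-of-ratios scaling, and in NK cells (0.10) with totals that left out mitochondrial and ribosomal genes. Later alternatives left out naive-like CD8 T cells or subclusters with high doublet scores, added the cycling subcluster or took 1 cluster alone. On simulated counts, all 100 genes changed 2-fold and all 100 changed 4-fold were recovered in CD8 T cells among 8018 genes, as the share 100.0% in each case. In monocytes and macrophages, 98.0% of 100 genes changed 2-fold and 100.0% of 100 changed 4-fold were recovered among 9289 genes. The 95% intervals held the true value for 95.3% and 95.2% of unchanged genes in these classes. The simulated counts had counting error alone, from rates shared by both libraries apart from the set changes, for genes with enough expected counts. They checked the calculation, and not differences between mice, libraries or cell make-up. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.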

Results

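CD45-positive cells sorted from B16-F10 melanoma tumors were compared between 1 Control library and 1 DOPAC library. In each library, RNA of single cells was counted as UMIs, which mark single captured transcripts. The 8079 kept Control cells held 91180798 UMIs, with a median of 9300.0 UMIs and 2735 genes per cell. The 9280 kept DOPAC cells held 41563537 UMIs, with a median of 3595.5 UMIs and 1523 genes per cell. Mitochondrial UMIs made up 3.24% of the kept Control UMIs and 3.67% of the kept DOPAC UMIs, and ribosomal protein genes 17.4% and 21.9%. Haemoglobin RNA made up 0.0984% of the Control UMIs and 0.0001% of the DOPAC UMIs. There was no replicate check of any difference given here, and all intervals are 95% intervals for counting error.

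The first comparison asked which leukocyte classes were found in the tumors of each group. T-like cells were the largest class in the DOPAC library, and monocyte and macrophage-like cells were the largest in the Control library. T-like cells made up 55.9% of DOPAC cells (54.9 to 56.9) and 21.5% of Control cells (20.6 to 22.4), a difference of 34.4 percentage points (33.0 to 35.7). Clustering at resolution 2.0 gave a difference of 21.9 points, and at resolution 0.5 of 22.9 points. NK-like cells were 17.5% of DOPAC and 13.3% of Control cells, a difference of 4.20 points (3.13 to 5.27). The other named lineages were smaller shares of the DOPAC library. Monocyte and macrophage-like cells were 17.8% against 31.7% in Control, dendritic-like cells 7.77% against 23.2%, and B-like cells 0.442% against 7.96%. Neutrophil-like cells were 0.345% of DOPAC and 1.5% of Control cells, and cells with melanoma genes such as Pmel, Mlana and Dct, which the CD45 sort should remove, were 0.194% and 0.780%. All shares were taken of a CD45 sort, so that 1 larger share lowers the others, and the DOPAC cells had fewer UMIs per cell. Among cells other than T cells, monocytes and macrophages were 40.4% of both libraries, NK cells 17.0% of Control and 39.8% of DOPAC cells, dendritic cells 29.6% and 17.6%, and B cells 10.1% and 1.00%.

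**Figure D1:**
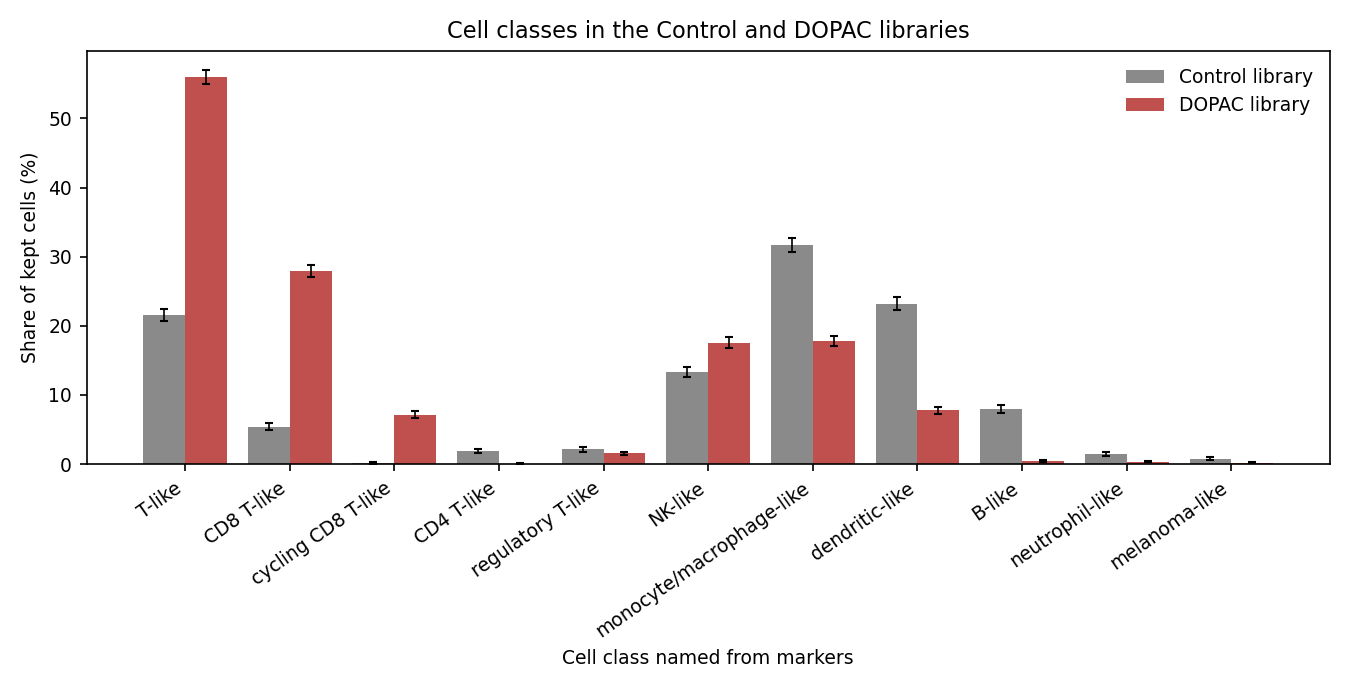
Share of kept cells (%) per named cell class in the Control and DOPAC libraries, with bars for 1 library each and exact 95% intervals for counting error. T-like cells were 21.5% of Control and 55.9% of DOPAC cells, and B-like cells 7.96% and 0.442%.

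Within the T lineage, CD8 T-like cells that were not cycling were 27.9% of DOPAC cells (2592 cells) and 5.41% of Control cells (437 cells), a difference of 22.5 points (21.5 to 23.6). A cycling CD8 T-like subcluster led by histone genes, Top2a and Kif11 held 665 DOPAC cells (7.17%) and 13 Control cells (0.161%). CD4 T-like cells were 0.0750% of DOPAC and 1.87% of Control cells, and this subcluster carried naive-cell genes such as Lef1, Tcf7 and S1pr1. Regulatory T-like cells with Foxp3 were 1.54% and 2.13%, but without 2 subclusters of high doublet score the Control share was 1.34% and the difference 0.204 points (-0.155 to 0.559), and gamma delta T-like cells with Il17a and Cd163l1 were 0.0970% and 0.668%. Some T cells were kept out of these classes by naming thresholds set after the data were seen. Cells that met neither the Cd8 nor the Cd4 rule made up 6.07% of DOPAC and 10.8% of Control cells. Of these, 494 DOPAC and 31 Control cells lay in 1 subcluster with Cd8 genes at 128 CPM and Cd4 genes at 4.3 CPM, and 19 and 424 in another at 48.1 and 7.1 CPM, both with Klra6 and Ikzf2 among their leading genes. Among the rest were 392 Control and 30 DOPAC cells of 1 subcluster led by Cd40lg, Cxcr3 and Gzmk. In it Cd8 genes reached 565 CPM and Cd4 genes 142 CPM, against 146 CPM for Cd4 genes in the CD4 T subcluster. Control T cells with Cd8 RNA therefore lay outside the CD8 T class, and cells with Cd4 or Cd40lg RNA outside the CD4 T class. The CD4 T shares above thus cover only the subcluster with naive-cell genes. Which of the cells left out were CD8 or CD4 T cells, and whether these had met antigen, was not tested. T cells of 2 subclusters with markers of another lineage among their leading genes, Cpa3 and Mcpt8 of basophils in 1 and Rora of innate lymphoid cells in the other, were 12.2% of DOPAC and 0.520% of Control cells. Their other leading genes included Gzmc, Gzmf, Icos and Cd6, which T cells express, and Cd8 genes were at 358 and 402 CPM. Shallow T cells were 0.862% and 0.0120%. Most T subclusters held cells of mainly 1 library, and for such a subcluster a cell type was not separable from a difference between libraries.

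Dendritic subsets were all smaller shares of the DOPAC library. The cDC1-like cells with Xcr1 and Clec9a were 1.80% of DOPAC and 5.31% of Control cells. The cDC2-like cells with Cd209a and Clec10a were 3.64% and 7.32%, mature DC-like cells with Ccr7 and Fscn1 1.49% and 4.54%, and plasmacytoid DC-like cells with Siglech 0.636% and 4.91%.

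The next comparison asked how the CD8 T cells of the groups differed in expression, since these cells are an effector class in such tumors. CD8 T-like cells of the DOPAC library carried more RNA of cytotoxic effectors and T-cell exhaustion genes, and those of the Control library more RNA of naive and stem-like genes. Gzmb, which encodes granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), was at 1222 CPM (1203 to 1241) in DOPAC and 104 CPM (93.5 to 114) in Control, 11.8-fold higher (10.7 to 13.1). Havcr2, which encodes TIM-3 (ENSMUSG00000020399, chromosome 11, 46454935 to 46481255), was at 231 and 18.0 CPM, 12.6-fold higher (10.1 to 16.6). Pdcd1, which encodes PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), was at 164 CPM (157 to 171) and 38.5 CPM (32.4 to 45.3), 4.23-fold higher (3.59 to 5.08). Prf1 was 5.11-fold and Ifng 4.98-fold higher in DOPAC, and Tox was 2.0-fold higher, at 846 and 423 CPM. Tcf7, which encodes TCF-1 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014), was at 11.7 CPM (9.96 to 13.7) in DOPAC and 295 CPM (278 to 313) in Control, 25-fold lower (21.3 to 29.9).

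The CD8 T class was drawn from different cells in the libraries. In Control, 394 of 437 cells, or 90.2% (87.0 to 92.8), belonged to a naive-like subcluster led by Lef1, Dapl1 and Tcf7. In DOPAC this held for 12 of 2592 cells, or 0.460% (0.240 to 0.810), and 1682 DOPAC cells came from a subcluster led by Cxcr6, Cd8a and Pdcd1 that held 6 Control cells. Without the naive-like subcluster, 43 Control and 2580 DOPAC cells were left, with median depths of 14484 and 4374 UMIs, and the median log2 ratio of all genes moved by -0.19. These cells still differed in make-up, since 25 of the 43 Control cells and 142 of the 2580 DOPAC cells lay in a subcluster led by Ccl1, Ptprk and Tnfsf11. In the 43 and 2580 cells Gzmb was higher in DOPAC at a log2 ratio of 1.33 (3.56 with the naive-like cells), Havcr2 at 1.42 (3.66), Prf1 at 1.15 (2.35) and Ifng at 0.76 (2.32). Prf1 and Ifng rested on 60 and 71 Control UMIs, at 2.22-fold (1.75 to 2.97) and 1.69-fold (1.36 to 2.21). Pdcd1 was at -0.23 (2.08) and Tox at -0.39 (1.00), and Tcf7 was at -2.38 (-4.64). Other members of the cytotoxic and exhaustion lists went both ways. Xcl1, a leading gene of the subcluster led by Ccl1, was 8.63-fold lower, Il2 32.6-fold from 28 Control UMIs, and Cd160 3.27-fold. Gzmf, Gzme, Entpd1 and Id2 were higher. In a gate on Cd8a or Cd8b1 UMIs without Cd4 UMIs, which held 723 Control and 3662 DOPAC cells, Gzmb was at 2.34, Pdcd1 at 1.15 and Tcf7 at -3.82. Clustering on cells thinned to 1000 UMIs put Gzmb at 0.95, Havcr2 at 1.77, Tox at 0.02, Pdcd1 at -0.08 and Tcf7 at -2.95.

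**Figure D2:**
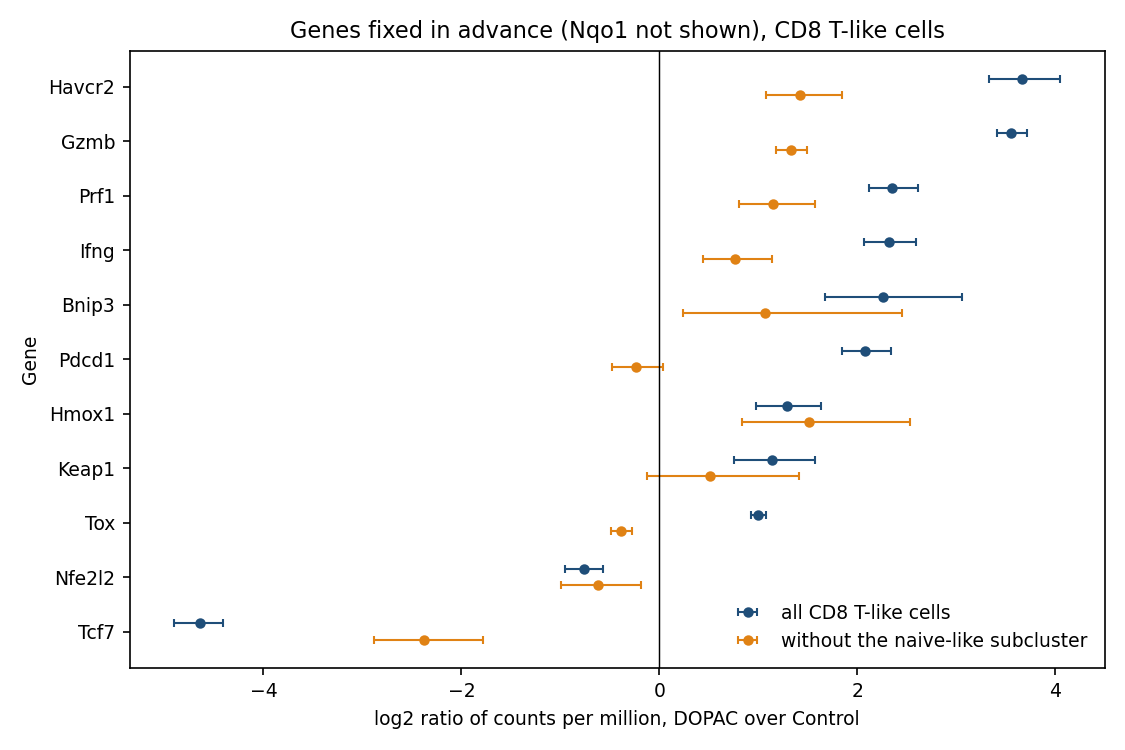
Log2 ratio of CPM, DOPAC over Control, for 11 of the genes fixed in advance in CD8 T-like cells, with 95% intervals for counting error, for all cells of the class and without the naive-like subcluster. Gzmb was at 3.56 and 1.33, and Pdcd1 at 2.08 and -0.23.

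After thinning to 1000 UMIs, 57.5% of DOPAC CD8 T cells (55.6 to 59.5) and 4.15% of Control CD8 T cells (2.48 to 6.48) had a Gzmb UMI. B cells, which should lack it, had one in 4.88% of 41 DOPAC cells and 0.469% of 640 Control cells at the same depth. Without thinning the CD8 T shares were 85.7% and 12.8%, at median depths of 4372.5 and 7589 UMIs. The B-cell shares were then 7.32% and 2.02%, at median depths of 1539 and 4284 UMIs. The Pdcd1 shares of thinned CD8 T cells were 15.2% in DOPAC (13.9 to 16.7) and 1.84% in Control (0.799 to 3.60), those of Havcr2 19.7% and 0.461%, and those of Lag3 6.80% and 0.461%. Tox was found in 50.3% and 23.7%, Ifng in 14.1% and 1.61%, Prf1 in 16.5% and 4.38%, and Gzmk in 5.16% and 0.230%. A subcluster with Gzmk among its leading genes and Cd8 genes at 565 CPM, of 392 Control and 30 DOPAC cells, lay outside this class. The Gzmk shares therefore do not describe all T cells with Cd8 RNA. Tcf7 was found in 0.977% of DOPAC cells (0.633 to 1.44) and 26.0% of Control cells (22 to 30.4) and Il7r in 2.97% and 33.9%. Control B cells showed Tcf7 in 0.625% and Pdcd1 in 0.156%, and 0 of 41 DOPAC B cells had Tcf7 or Pdcd1, which allows a share of up to 7.32%. Mki67 was found in 5.0% and 0.461% of thinned CD8 T cells and Top2a in 5.40% and 1.84%. The cycling subcluster of 665 DOPAC and 13 Control cells, kept apart by these same genes, was not part of the class. The B-cell shares in DOPAC and Control were 4.88% and 0.469% for Tox, 4.88% and 0.156% for Ifng, 2.44% and 0.625% for Prf1 and 7.32% and 1.25% for Top2a. No DOPAC B cell had Havcr2, Lag3, Gzmk, Mki67, Il7r or Bnip3, again with a limit of 7.32%. The upper bound for Ifng in DOPAC B cells was 16.5%. The DOPAC CD8 T shares of Lag3, Gzmk, Ifng, Mki67, Top2a, Il7r and Tcf7 were therefore not separable from background. Bnip3 was found in 1.88% and 0.461% of thinned CD8 T cells and in 1.56% of Control B cells, so that background was not excluded for it either. Hmox1 was found in 3.95% and 1.38%, below its B-cell shares of 4.88% and 1.88%, and was read as background. In thinned cells without the naive-like subcluster, Gzmb was found in 57.9% of DOPAC and 26.8% of 41 Control cells, Pdcd1 in 14.9% and 17.1%, Tox in 52.2% and 61.0%, and Lag3 in 6.72% and 7.32%.

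Genes of CD8 T cells were ranked among those that could be named, without library-wide genes. The 10 most raised in DOPAC included 2 granzyme genes, 2 metallothionein genes and genes that other cells express too. Gzmf had 497 UMIs in DOPAC and 0 in Control, at least 46.3-fold higher, and Gzmc was 24.2-fold higher (11.7 to 111) from 4 Control UMIs. Mt3 had 570 DOPAC and 7 Control UMIs, and Ctnnd2 was 19.3-fold, Mt2 17.9-fold and Ank3 16-fold higher. Klrc2, at 169 and 11.3 CPM, was also expressed by NK cells at 182 and 172 CPM. Cxcl9, at 90.5 and 5.65 CPM, and Fgl2, at 99.3 and 6.19 CPM, are myeloid genes too, and monocytes and macrophages had more of both, with Cxcl9 at 1074 and 251 CPM and Fgl2 at 330 and 93.1 CPM. Csf1 was at 43.2 and 2.69 CPM. The lowest genes in DOPAC were Tdrp (49.0-fold), Rflnb (44.1-fold), Cxcr5 (40.3-fold), Auts2 (37.6-fold), Nsg2, St8sia1, Klf2 (34.5-fold; ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), S1pr1 (30.9-fold), Cmah and Cd163l1. Tdrp, Auts2, Nsg2 and Cmah, like Lef1 and Tcf7, were leading genes of the naive-like subcluster, and Rflnb, St8sia1 and S1pr1 of a T-cell cluster also led by Lef1 and Tcf7, so that these genes took part in the grouping. Without the naive-like subcluster Klf2 was at a log2 ratio of -0.61, Gzmc at 2.18, Mt3 at 1.90 and Mt2 at 2.22.

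The T-cell lists followed the same division. The naive and stem-like list had a median log2 ratio of -3.29, with all 14 of 14 members at least 1.5-fold lower, among them Cxcr5, Klf2, S1pr1 and Lef1. T-cell exhaustion was at 2.09 with 15 of 16 members higher, including Entpd1, Id2 and Cd38. Cytotoxic effectors were at 1.75 with 17 of 22 higher and 2 lower. The exhaustion and cytotoxic medians lay above all and the naive median below all of the random lists. Without the naive-like subcluster the naive list was at -0.85, cytotoxic effectors at 0.70 and exhaustion at 0.17, and with clustering on thinned cells they were at -1.70, 0.46 and 0.26. In the gated cells cytotoxic effectors were at 0.85, and at clustering resolution 2.0 at 1.00. T-cell activation was at 0.14, with 5 of 15 members higher, such as Tnfrsf9 and Icos, and Cd69 and Myc lower. Proliferation was at 1.10 with 21 of 23 higher, but at -0.43 without the naive-like subcluster and at -0.15 with clustering on thinned cells. These values leave out cells kept apart as cycling by Mki67 and Top2a, which are members of this list. In the main clustering those were 665 DOPAC and 13 Control cells, so the list does not describe proliferation of all CD8 T cells. Chemokine receptors were at -0.46, with Cxcr6 and Cx3cr1 higher and Cxcr5 lower. TGF-beta and residency genes were at -0.62, with Itga1 higher and Itgae lower, and at 0.44 without the naive-like subcluster. Apoptosis and p53 genes were at 0.54, with Bcl2, Bbc3 and Fas lower, and at -0.02 without the naive-like subcluster.

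Lists on oxidative stress and mitochondria were included because DOPAC is a catechol, a kind of molecule that takes part in oxidation. NRF2 targets, the genes of the antioxidant response, were at 0.41, with 8 of 18 members higher and 0 lower, at percentile 97.4. Osgin1 was 11.3-fold higher, Slc7a11 2.86-fold, Txn1 2.55-fold, and Srxn1 was at a log2 ratio of 1.71. This median was -0.13 without the naive-like subcluster, -0.35 with clustering on thinned cells, 0.03 at resolution 0.5, 0.17 in the gated cells and 0.07 without subclusters of high doublet score. Nfe2l2, which encodes NRF2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641), was 1.70-fold lower in DOPAC (1.49 to 1.93), at 54.4 and 92.3 CPM, a log2 ratio of -0.76, which was -1.42 without subclusters of high doublet score, -1.31 at resolution 0.5 and -0.57 with doublets kept. Keap1, which encodes its repressor (ENSMUSG00000003308, chromosome 9, 21229730 to 21239361), was 2.19-fold higher (1.69 to 2.98), at 34.7 and 15.6 CPM, and at a log2 ratio of 0.51 without the naive-like subcluster, 0.21 with clustering on thinned cells and 2.15 after thinning. Hmox1 was at a log2 ratio of 1.29, but at -0.20 with resolution 0.5, -0.19 in the gated cells, -0.56 with clustering on thinned cells and -0.17 without subclusters of high doublet score, and macrophages expressed it at 940 and 954 CPM. Nqo1 had 11 DOPAC and 2 Control UMIs, a ratio of 1.12 (0.336 to 14.3), so that no difference was detectable at this depth. The NRF2 pathway list was at 0.04 with 2 of 9 higher and 3 lower, Mafg being higher and Bach2 and Maff lower. Mitophagy was at -0.08 with 3 of 21 higher and 6 lower. Bnip3, for which background was not excluded, was 4.79-fold higher in DOPAC (3.20 to 8.32), at 27.0 and 5.38 CPM, and at a log2 ratio of 1.06 without the naive-like subcluster and 0.09 with clustering on thinned cells. Pink1 was at a log2 ratio of -1.99.

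Lists of energy metabolism were higher in the DOPAC class as a whole, and 3 of them were no longer higher without the naive-like cells. Nuclear OXPHOS genes were at 0.68 with 21 of 36 higher, including Atp5k, Ndufc1 and Cox6c, glycolysis at 0.57 with 7 of 17 higher, including Ldha, and 1 lower, Pfkl, and hypoxia at 0.81 with 10 of 14 higher, including Mxi1, and 2 lower, including Pdk1. Without the naive-like subcluster these medians were -0.25, -0.75 and -0.18, with the median of all genes at -0.16, so that OXPHOS and hypoxia lay near the level of all genes. With clustering on thinned cells they were -0.22, -0.82 and -0.44, with all genes at -0.13. Mitochondrially encoded genes were at 0.12 with 5 of 13 higher, and mt-Nd4l alone was 13-fold higher, at 921 and 70.5 CPM. Cholesterol and lipid genes were at 0.57, with Cd36 and Acadl higher and Abcg1 lower, and at -0.44 without the naive-like cells. The unfolded protein response was at 0.21, with Hsp90b1 higher, and at -0.35 without them.

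Interferon response genes in CD8 T cells were at 1.02 with 20 of 27 higher and 0 lower, above all random lists, and at 0.85 without the naive-like subcluster. This median was 0.57 in the gated cells, 0.61 at resolution 0.5, 0.40 with clustering on thinned cells and 0.56 without subclusters of high doublet score. Rsad2, Ifi27l2a and Oasl1 were at log2 ratios of 2.19, 2.16 and 1.84. MHC class I was at 0.29 with 4 of 14 higher, such as Tap1 and B2m, and at -0.32 without the naive-like cells. Some myeloid and antigen-presentation lists depended on subclusters of median doublet score above 0.1, which held 447 DOPAC and 8 Control cells. MHC class II was at 0.29, inflammatory myeloid genes at 0.86 and alternatively activated macrophage genes at 0.41, and without these subclusters they were at -1.31, -0.55 and -1.47. Heat shock and dissociation stress genes were at -0.38, with Jun, Junb and Ier2 among 9 of 23 lower. Of the remaining lists, aryl hydrocarbon receptor was at -1.39 over 3 members with Ahr and Lpar6 lower, and dopamine handling at -0.35 over 5 members. Small-subunit ribosomal proteins were at -0.40 and nuclear-retained RNA at 0.26. Melanoma cell RNA was at 0.50 over 6 members and at -0.22 under the stricter cell filter, and erythrocyte RNA was at -4.54 over 3 haemoglobin genes.

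The other classes were compared to learn which differences were seen in 1 class and which across classes. Interferon response genes were higher in the DOPAC library in all 7 classes compared, above all random lists in each. Their median was 1.29 in cDC2, 1.25 in monocytes and macrophages, 1.08 in mature DCs, 1.02 in CD8 T cells, 0.92 in regulatory T cells, 0.81 in cDC1 and 0.72 in NK cells. Iigp1, an interferon-induced GTPase gene (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), was 2.02 to 11.8-fold higher over the classes, and in monocytes and macrophages it was at 127 CPM (119 to 136) in DOPAC and 13.4 CPM (12.3 to 14.7) in Control. Other members were chosen after their values were seen: Gbp4 was 1.65 to 5.97-fold higher, Irgm1 1.79 to 4.93-fold and Gbp2 1.76 to 3.97-fold. Taken cluster by cluster, the median was between 0.67 and 1.53 in monocytes and macrophages, and it was 0.32 in NK cluster 1 alone.

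**Figure D3:**
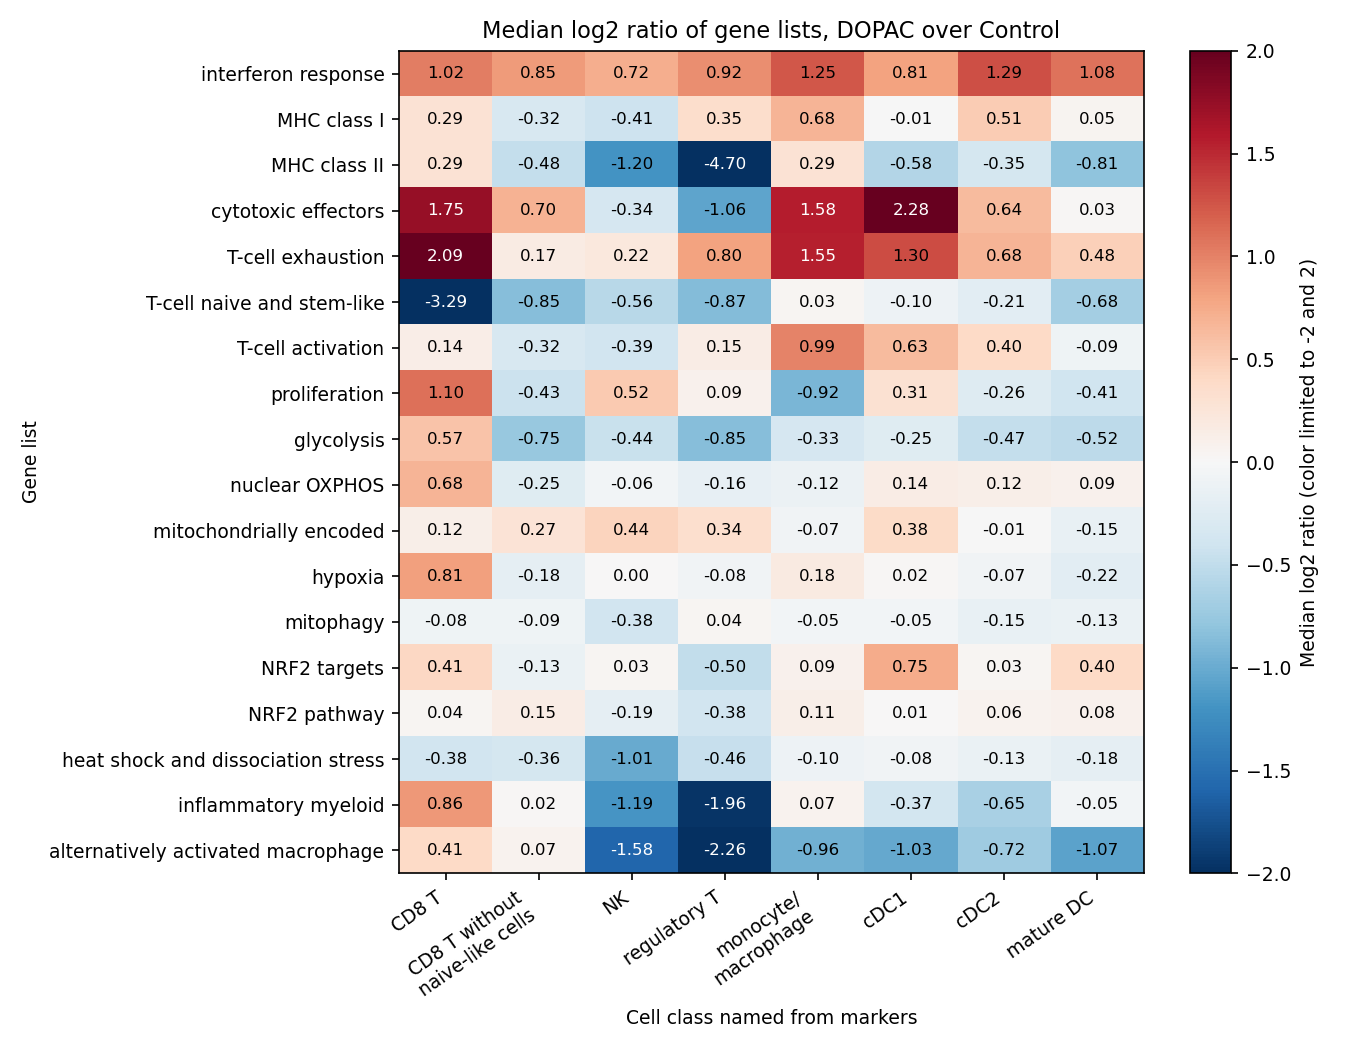
Median log2 ratio, DOPAC over Control, of 18 gene lists in 7 cell classes and in CD8 T-like cells without the naive-like subcluster, with the value printed in each field and colors ending at -2 and 2. Interferon response was above 0 in every column, from 0.72 in NK cells to 1.29 in cDC2, and glycolysis was above 0 only in the whole CD8 T class, at 0.57.

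Of the genes that could be named in any class, 72 were at least 1.5-fold higher and 64 lower in every class where they were measured. Mitochondrial, ribosomal and haemoglobin genes were left out of these counts and of the ranking that follows. The highest by median log2 ratio over classes were Filip1 (3.31), Cxcr6 (2.95), Gzmb (2.71), Iigp1 (2.57) and Cd8a (2.42). The lowest were Apoe (-3.16), Cd79a (-2.78), Igfbp4 (-2.76), Ccl17 (-2.60) and Pf4 (-2.35). Gzmb, Cxcr6 and Cd8a are T-cell or killer-cell genes, Cd79a is a B-cell gene and Apoe and Pf4 are macrophage genes, and the share of each of these cell types differed between the libraries in the same direction. The higher genes included 8 interferon response members, among them Gbp2, Ifit1 and Xaf1.

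Monocytes and macrophages of the DOPAC library had more RNA of interferon response and MHC class I genes and less of alternatively activated macrophage genes. Gbp2b was 27.0-fold higher (20.2 to 38.0), at 37.6 and 1.37 CPM, Nlrc5 2.97-fold and B2m 2.22-fold. MHC class I was at 0.68 with 9 of 14 members higher, and between 0.08 and 1.04 in single clusters, and MHC class II was at 0.29. Nos2 was 4.77-fold and Il6 2.13-fold higher, although inflammatory myeloid genes together were at 0.07. Fcrls had 4 DOPAC and 1549 Control UMIs, 60.4-fold lower, Gas6 was 18.1-fold and Cela1 7.95-fold lower, and Mir99ahg and Rapgef5 followed. Trem2 was 4.88-fold lower and Apoe 4.29-fold lower, at 402 and 1726 CPM, and both were library-wide genes. Alternatively activated macrophage genes were at -0.96 with 13 of 20 members lower, and between -0.74 and -0.06 in single clusters. This list was below 0 in all 6 classes other than CD8 T cells, from -0.72 in cDC2 to -2.26 in regulatory T cells. It was at -1.58 in NK cells, so its difference was not particular to monocytes and macrophages. The clusters contributed unequally: the cluster led by C1qa, Gas6 and Fcrls held 471 Control and 66 DOPAC cells, that led by Arg1 and Spp1 876 and 288, and that with Gbp2 and Cxcl9 660 and 834. Proliferation was at -0.92 in the whole class but between -0.77 and 0.87 in single clusters. T-cell RNA was also higher in these cells, with Cd3g at 28.6 and 3.64 CPM and Tox 7.57-fold higher beside Ccdc162 and Tmem267, and cytotoxic effectors at 1.58 and T-cell exhaustion at 1.55. NRF2 targets were at 0.09 in this class.

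NK cells of the DOPAC library had less RNA of immediate-early and heat shock genes. This list was at -1.01 with 15 of 23 members lower, below all random lists, and Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718) was 4.96-fold lower (4.71 to 5.22), Ier2 4.03-fold and Hspa1a 3.59-fold. In cluster 1 alone, which held 1516 DOPAC and 59 Control cells, the median was -1.12; the Control NK cells were mostly in cluster 5 with 1013 Control and 45 DOPAC cells. Of the granzyme genes, Gzmd had 127 DOPAC and 0 Control UMIs, at least 59.4-fold higher, and Gzmc was 2.57-fold higher. Cytotoxic effectors as a list were at -0.34. Ctnnd2, Pclaf, Pdgfa, Spp1 and Gpat3 were 3.67 to 5.13-fold higher. Of the genes that could be named, without library-wide genes such as Junb, the lowest were Spi1, Cd14, Klf2, Ier2 and H2-DMb1. Spi1, Cd14 and H2-DMb1 are myeloid genes, and MHC class II was at -1.20. Klf2 was 4.44-fold lower. Proliferation was at 0.52 in NK cells with 11 members higher, but at 0.13 after thinning and at -0.81 in cluster 1 alone. Mitophagy was at -0.38 with 9 of 21 members lower, and dopamine handling at 0.66 with 3 of 5 higher.

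In dendritic cells, antioxidant genes were higher in the cDC1 subset and antigen-presentation genes of class II lower in all 3 subsets compared. NRF2 targets in cDC1 were at 0.75 with 10 of 18 members higher, above all random lists, with Hmox1 2.90-fold, Srxn1 2.80-fold, Osgin1 2.61-fold and Slc7a11 2.60-fold higher. Melanoma cell RNA was at 1.36 in cDC1 over 3 members, so that RNA of other cells moved with this list. NRF2 targets were at 0.40 in mature DCs and 0.03 in cDC2 and in NK cells, and at -0.50 in regulatory T cells. MHC class II was at -0.58 in cDC1, where Cd74 was 1.95-fold lower, at -0.35 in cDC2 and at -0.81 in mature DCs. In cDC2, MHC class I was at 0.51 with 6 of 14 higher. Genes of the 3 dendritic subsets were ranked among those that could be named, without library-wide genes such as Iigp1. Tgtp1 (9.21-fold), Clec9a, Tmem163, Batf2 (6.26-fold) and Cxcl9 (5.78-fold) ranked highest in cDC2. F10, Vcan, Tnfsf4, Ear2 and Pgf were 4.24 to 5.68-fold lower in cDC2. In cDC1 the highest genes included the lymphocyte genes Klrc1 (30.5-fold) and Ms4a4b (12.1-fold), besides Tmem163, Setbp1 and Ccdc162, and cytotoxic effectors were at 2.28 there. Tpcn1 (6.61-fold), Tnfsf9 (4.95-fold), Gpr4, Uap1l1 and Arhgap22 were the lowest in cDC1. In mature DCs Dennd5b (6.19-fold), Il23r (5.07-fold), Pde7b, Il6 (4.59-fold) and Naa25 were highest. Peli2 (160 Control and 0 DOPAC UMIs) was at least 7.75-fold lower and Bank1 at least 6.15-fold lower, followed by Fabp4, Zfp704 and Ebf1. Bank1 and Ebf1 are B-cell genes.

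Regulatory T cells of the DOPAC library had more RNA of T-cell exhaustion genes and less of glycolysis genes. T-cell exhaustion was at 0.80 with 9 of 15 members higher, with Lag3 8.68-fold, Tigit 3.41-fold and Entpd1 3.16-fold higher and Cd244a lower, with 1 DOPAC and 41 Control UMIs. It was between 0.42 and 0.49 at resolution 2.0, with clustering on thinned cells and after thinning. The list was above 0 in all 7 classes compared, and CD8 T-cell RNA was also higher in the DOPAC regulatory T cells, with Cd8a at 33.2 and 11.5 CPM, so that RNA of CD8 T cells was not excluded as a part of it. Glycolysis was at -0.85 with 11 of 17 members lower, and at -0.28 over 13 members after thinning. Of the genes that could be named, without library-wide genes, Myo1d (5.04-fold), Setbp1, Cep112, Cysltr2 and Kif20b were the highest. Of the 172 Control cells, 64 lay in 2 subclusters of high doublet score that held no DOPAC cell and carried dendritic-cell RNA. The lowest genes in the same ranking were Ifitm1 (at least 94.8-fold), Htr7, Slc8a1, Cd209a and Spi1. They had most of their Control UMIs in these cells, 1380 of 1401 for Ifitm1 and 323 of 344 for Spi1. The MHC class II median was -4.70, and -1.18 without them. NRF2 targets were at -0.50 with 8 of 17 members lower, at percentile 0.255, with Slc7a11 5.28-fold and Hmox1 4.44-fold lower, and at -0.13 without those subclusters. Without those subclusters cytotoxic effectors turned from -1.06 to 0.22.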

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

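The alternatives that left out the naive-like CD8 T subcluster, left out subclusters of high doublet score, added the cycling subcluster or took 1 cluster alone were chosen after seeing the data, as was the set of list medians followed in the other classes; the rest were planned. No paired analysis was possible because there was 1 library per group. For 125 results, 1339 alternative values were computed: 824 stayed within the counting interval of the reported value, 452 moved out of it with the same direction or from a value not distinct from 0, and 63 reversed. For the CD8 T list medians these numbers were 264, 147 and 41 of 452, for list medians in the other classes 219, 99 and 7 of 325, for genes named in CD8 T cells 315, 157 and 8 of 480, and for marker shares 5, 33 and 7 of 45. The 6 class shares followed in this way, of T, CD8 T, NK, dendritic and B cells and of monocytes and macrophages, kept their direction under every alternative run. The cause of a change was not tested unless stated.

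With the stricter cell filter, the difference in share between DOPAC and Control was 32.49 points for T cells, 19.92 for CD8 T cells and -6.05 for B cells, and in CD8 T cells cytotoxic effectors were at 1.97 and melanoma cell RNA at -0.22. With every barcode of at least 200 genes, the differences were 32.85 points for T, 26.31 for CD8 T, -14.23 for dendritic and -6.79 for B cells, and cytotoxic effectors were at 1.99. With doublets kept, they were 36.4 for T and 29.35 for CD8 T cells, with NRF2 targets at 0.58, naive and stem-like genes at -3.13 and MHC class II at -0.04. At resolution 0.5 they were 22.88 for T and 19.29 for CD8 T cells, NRF2 targets were at 0.03, MHC class II at -1.28, inflammatory myeloid genes at -0.70, alternatively activated macrophage genes at -1.40, melanoma cell RNA at -1.78 and Hmox1 at -0.20. At resolution 2.0 they were 21.87 for T, 18.48 for CD8 T and -13.37 for dendritic cells, with mitophagy at -0.25, cytotoxic effectors at 1.00, exhaustion at 1.74 and naive genes at -2.80.

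Many values changed with clustering on cells thinned to 1000 UMIs. Monocytes and macrophages then differed by -10.4 points. In CD8 T cells, NRF2 targets were at -0.35, mitophagy at -0.22, nuclear OXPHOS at -0.22, glycolysis at -0.82, hypoxia at -0.44, cytotoxic effectors at 0.46, exhaustion at 0.26, naive genes at -1.70, proliferation at -0.15, MHC class I at -0.38 and MHC class II at -1.17. Inflammatory myeloid genes were at -0.69, alternatively activated macrophage genes at -1.37, the unfolded protein response at -0.56, cholesterol and lipid at -0.46, TGF-beta and residency at 0.80, melanoma cell RNA at -1.69, Pdcd1 at -0.08 and Hmox1 at -0.56. In cells gated by Cd8a or Cd8b1 and no Cd4, NRF2 targets were at 0.17, mitophagy at -0.25, cytotoxic effectors at 0.85, exhaustion at 1.52, naive genes at -2.73, MHC class I at -0.06, MHC class II at -0.16, alternatively activated macrophage genes at -0.31, melanoma cell RNA at -0.13 and Hmox1 at -0.19.

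Without the naive-like subcluster, which by construction removes 394 of the 437 Control cells, NRF2 targets were at -0.13, nuclear OXPHOS at -0.25, glycolysis at -0.75, hypoxia at -0.18, cytotoxic effectors at 0.70, exhaustion at 0.17, naive genes at -0.85 and proliferation at -0.43. MHC class I was at -0.32, MHC class II at -0.48, apoptosis and p53 at -0.02, the unfolded protein response at -0.35, cholesterol and lipid at -0.44 and TGF-beta and residency at 0.44. Pdcd1 was at -0.23 and Tox at -0.39. Auts2 was at 0.20 from 0 Control and 21 DOPAC UMIs, so that this value is set by the added count and gives no direction. The thinned marker shares then differed by -2.19 points for Pdcd1, -0.60 for Lag3, -8.82 for Tox, -4.17 for Tcf7, 31.1 for Gzmb, -0.08 for Bnip3 and -0.75 for Hmox1, against 13.4 for Pdcd1, 53.4 for Gzmb and -25.06 for Tcf7 in the whole class. Without subclusters of median doublet score above 0.1, NRF2 targets were at 0.07, exhaustion at 2.30, naive genes at -4.03, MHC class II at -1.31, inflammatory myeloid genes at -0.55, alternatively activated macrophage genes at -1.47, cholesterol and lipid at -0.06 and Hmox1 at -0.17. With the cycling subcluster added, the CD8 T share differed by 29.53 points, exhaustion was at 1.72, naive genes at -3.44 and MHC class II at -0.13.

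Of the scalings, totals without mitochondrial and ribosomal genes gave mitophagy at -0.17 in CD8 T cells and interferon response at 0.83 in NK cells. With the mean over cells, cytotoxic effectors were at 2.17, exhaustion at 2.59 and naive genes at -3.53 in CD8 T cells. With each cell thinned to 1000 UMIs these were at 2.05, 2.38 and -3.63, and the unfolded protein response was at -0.08; with list members of at least 1 UMI it was at -0.06. Without thinning, the marker shares differed by 40.24 points for Pdcd1, -78.52 for Tcf7, 72.91 for Gzmb and -2.19 for Hmox1, and with thinning to 2000 UMIs by 24.16, -45.48 and 68.88 points for Pdcd1, Tcf7 and Gzmb. These shares depend on depth by construction, since a deeper cell has more chances of a UMI.

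In regulatory T cells without the subclusters of high doublet score, the NRF2 pathway was at 0.14, cytotoxic effectors at 0.22 and T-cell activation at -0.01. In monocytes and macrophages, interferon response was at 0.67 in cluster 2 alone, 1.53 in cluster 4, 0.77 in cluster 11, 1.18 in cluster 14 and 1.17 in cluster 17, and proliferation was at 0.87 in cluster 2, 0.06 in cluster 4 and 0.16 in cluster 11. In NK cluster 1 alone, interferon response was at 0.32 and proliferation at -0.81. Depth limits the genes near the detection limit, such as Nqo1 with 2 and 11 UMIs in CD8 T cells, and every value without the naive-like subcluster, which rests on 43 Control cells.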

Other observations

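The tests on CD8 T-cell make-up by depth, blood or lymphoid cells and treatment, on NRF2 targets and on the transcript length of genes shifted in every class were chosen only after the result was seen; the others were written beforehand. Beyond the comparisons above, glycolysis genes were lower in the DOPAC library in all 6 classes other than CD8 T cells, with medians from -0.25 in cDC1 to -0.85 in regulatory T cells. Pfkl, chosen after its values were seen, was 1.51 to 2.74-fold lower over the 7 classes. Heat shock and dissociation stress genes were below 0 in 7 of 7 classes, from -0.08 in cDC1 to -1.01 in NK cells, with Junb 1.53 to 5.66-fold lower. A set of mitochondrial and ribosomal genes, also chosen after their values were seen, was higher in every class: mt-Nd4l by 8.97 to 15.9-fold, mt-Atp8 by 2.94 to 6.58-fold, mt-Nd5 by 2.03 to 3.56-fold, Rps28 by 1.45 to 2.63-fold and Rps29 by 1.32 to 2.43-fold. In contrast, mt-Co3 was lower in 7 of 7 classes, by 1.17 to 1.88-fold.

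For genes shifted in every class, 2 technical candidates were tested, free RNA and transcript length. Other differences between the libraries, such as handling, were not tested. If free RNA from the more frequent cell types of a library were the source, at least 50% of these genes should have had 1 class at 10 times the median class. Of the 64 genes lower in every class of the DOPAC library, 35.9% (24.3 to 48.9) had such a class in Control, against 12.8% of other genes, and of the 72 higher genes 27.8% (17.9 to 39.6) did in DOPAC, against 12.2%. The test undercounts genes such as Cd8a, Gzmb and Cxcr6 that several T and NK classes express. It found 73 of 82 markers of the lineages of larger share in Control and 22 of 28 in DOPAC, and raised for markers missed, a correction chosen after the shares were seen, the upper bounds of the shares were 54.9% and 50.4%. Free RNA and other sources therefore cannot be told apart for these genes, and the shares above those of other genes leave free RNA a candidate source for part of them. The longest transcripts of the higher genes had a median length 1.81 times (1.35 to 2.10) that of the lower genes, and whether a length difference between libraries or the genes' function sets this cannot be told apart, since the interval reaches below the limit of 1.5 set for it.

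The effector-like state of DOPAC and the naive-like state of Control CD8 T cells was weighed against depth, mixed cells, tissue source and treatment. For depth, T cells were named by clustering on cells thinned to 1000 UMIs and gated by their thinned Cd8a, Cd8b1 and Cd4 UMIs, which left 312 Control and 1881 DOPAC cells. In the full counts of these cells, naive, cytotoxic and exhaustion genes were at -2.89, 0.89 and 1.56, against -2.73, 0.85 and 1.52 with the gate at full depth. The lowest share of a median kept was that of exhaustion, 102.2% (81.9 to 117.3 over resampled cells). For cytotoxic effectors it was 104.1% (80.4 to 144.6). This argues against an effect of depth on the choice of cells as the cause in gated T cells. An effect of depth on the compared counts was not part of this test. In the class named by clustering, the share of the pattern that depth accounts for cannot be told apart from the naming of cells. With clustering on thinned cells that class held 62 instead of 437 Control cells, with naive genes at -1.70 (-3.29 at full depth), cytotoxic effectors at 0.46 (1.75) and exhaustion at 0.26 (2.09). Without subclusters of high doublet score, which held 447 DOPAC and 8 Control cells, cytotoxic effectors were at 1.87 (1.75 with them). The difference in this list therefore did not rest on those subclusters. Mixed cells in the rest of the class were not tested, since most cells of the class stayed in. More blood or lymphoid-tissue cells in the Control library remain a candidate explanation, because CD4 T cells with naive genes, B cells and plasmacytoid DCs were all larger shares of Control, by 7.73 to 24.78 times. Haemoglobin RNA was also 0.0984% of kept Control and 0.0001% of kept DOPAC UMIs, and erythrocyte RNA was below 0 in all 7 classes. The DOPAC treatment and such a difference in tissue or handling cannot be told apart with 1 library per group.

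NRF2 targets were at 0.41 in CD8 T cells, and 2 explanations for this were tested. Without the naive-like subcluster the median was -0.13, and without the subclusters of high doublet score, which carry myeloid RNA, it was 0.07. Both values are what the make-up of the class as the source would give, and either may be sufficient. Neither separates make-up from a change within cells, since the first leaves 43 Control cells. The second removes 447 DOPAC cells of subclusters whose leading genes also include Gzmb, Gzmc and Pdcd1. The list's median in this class therefore gives no ground for a change within CD8 T cells, and does not exclude one.

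A hypothesis of short transcripts was negative. The nuclear OXPHOS list holds short transcripts, and a difference between the libraries by transcript length could have raised it, with short transcripts higher in every class. The difference in median log2 ratio between short and long transcripts ranged from -0.29 to 0.19 over the 7 classes, and not at the 0.2 that the hypothesis needed in each of them. Without mitochondrial and ribosomal genes it was 0.216 in CD8 T cells and below 0 in 5 classes. Matched on length as well as expression, the OXPHOS list in CD8 T cells stayed at percentile 99.93, with its median at 0.68 and that of the random lists at 0.20. Transcript length therefore did not account for the whole difference.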
